A study of Mus musculus with 4 samples.

How the data were processed

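Total RNA of white adipose tissue was extracted with RNAiso Plus and turned into biotin-labelled cRNA with the Illumina TotalPrep kit, per the labels' protocols, and hybridised to 4 Illumina mouse bead arrays. Per the labels, 1 array held a mix of 3 chow samples and 3 arrays a mix of 4 high fat samples each, of the F0, F1 and F2 generations. The labels do not say whether the mixed samples came from separate animals. The submitters' processing notes name GenomeStudio 2010.2.

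The deposited table holds, per probe and array, an intensity on a linear scale and a detection p-value. The deposited intensities have the same mean of 274.4 on each array, so the arrays appear to be scaled to a common mean, a step that the labels do not state, and no value lies at or below 0. The deposited p-value moves in steps of 1 in 936, so 936 negative control bead types stand behind it. A value table of the authors holds a background-subtracted intensity: on each array it is a straight-line function of the former table with slopes from 0.987 to 1.01, a mean of 216.4, and 25.8 to 27.8% of values below 0. Its column medians are 6.17 for chow, 5.69 for F0, 5.61 for F1 and 6.24 for F2, and it is not on a log scale and not centred by probe. It served as an alternative. No bead-level error was used here, and 0 columns of per-sample values were left unused.

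Background was corrected with the nec function of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization across the 4 arrays and log2. A probe counted as detected at a detection p below 0.01. The lowest detected log2 signals were 4.82, 4.89, 4.94 and 4.77 on the chow, F0, F1 and F2 arrays. Detected probes numbered 18011, 17435, 17095 and 18532 in the same order, and 15318 were detected on all 4 arrays. Probe names came from the platform annotation, in which 34885 of 45281 probes have 1 gene symbol, 18 several and 10378 none. For 34807 probes the symbol was updated through or matched by the gene ID, and 78 kept the symbol of the annotation. Of 20780 probes detected on at least 1 array, 17582 had 1 symbol and gave 11384 genes, each represented by its brightest probe. Over 3069 genes with several probes detected on all arrays, the other probe had the same sign in 308 of 320 genes at least 2-fold apart for F0 against chow, 313 of 326 for F1, 386 of 399 for F2, 5 of 5 for F1 against F0, 65 of 66 for F2 against F1 and 136 of 139 for F2 against F0. The SD between probes of a gene was 0.162, 0.213 and 0.239 in the last 3.

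With 1 array per group, the 6 comparisons between arrays were described by size with no test. A gene counted where the log2 difference was at least 1 and the brighter array detected it. Across genes the arrays correlated at r = 0.934 (chow and F0), 0.929 (chow and F1), 0.908 (chow and F2), 0.989 (F0 and F1), 0.972 (F1 and F2) and 0.957 (F0 and F2), and genes are not independent replicates. A test was run where several arrays could be pooled. Limma's lmFit and eBayes with a mean trend compared 3 high fat arrays with 1 chow array, with 2 residual degrees of freedom, and fitted a slope over the 3 generations, with 1 residual degree of freedom. Both were two-sided with Benjamini-Hochberg adjustment at 0.05 over 11384 genes. Nothing says that the 3 high fat arrays are replicates, so the spread in these fits includes differences between generations. The fitted noise may also hold technical spread.

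The 43 gene lists were written before the data were examined, and so were the rule for named genes, the tests and most alternatives. The rule took, among genes detected on both arrays with a regular symbol and agreement in sign of their detected probes, the 12 largest increases and decreases against chow, 10 each for F2 against F0, and 5 each for F1 against F0 and F2 against F1. It took 10 each by limma p over the 3 high fat arrays, 8 each by F2 minus F0 difference among genes whose 3 generations are in order, up to 5 bounds each way, up to 4 members per list, and 15 genes given throughout. Dnmt3a was the 1 of those 15 that was detected on no array. Counts used detection of a gene by any probe, and bounds that of the brightest probe, which gives the gene its value; requiring it for the counts, an alternative added after the data were seen, left each as it was. Lists of hepatocyte, smooth muscle and pituitary genes were added after the data were seen, as were the scaling to probes detected on all arrays, a limma fit with undetected signals raised to the lowest detected signal of their array, a no-change reference for the order of generations (100 simulated sets) and the counts without genes of other tissues. A list was described by its median difference, whose percentile was taken among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. For the pooled fits, limma's camera was run with a preset correlation of 0.01 and with an estimated one. The latter rests on the residual degrees of freedom of the fit, 2 and 1, so few lists can pass it and a failure decides nothing.

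The scripts were tested on simulated data with 200 changed genes, drawn with limma's moderated spread of the high fat arrays as noise. The diet fit recovered 17.9% of changes of log2 1, 92.5% of log2 2 and 100% of log2 4, and called 17 unchanged genes. The slope fit recovered 1.5%, 83.6% and 97% and called 17 unchanged genes. The size rule recovered 40.3% of changes of log2 1 for F0 against chow and 58.2% for F2 against F0, the lowest and highest of the 6 comparisons. In these simulations 201 to 240 unchanged genes lay at least 2-fold apart. The simulated noise holds differences between generations, so this is no measure of noise alone. For F1 against F0 it gave 205 such genes, whereas the real arrays had 103 genes apart in all. Of 200 unchanged lists, 7 to 14 fell outside the central 95% of random lists, and 50 of 50 lists shifted by 0.5 lay above it. Alternatives were the authors' value table with a floor of 16, no background correction, median scaling, an offset of 50, other detection filters, the mean of a gene's probes, a 1.5-fold threshold, eBayes without a mean trend, and leaving out each high fat array. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the tables and figures.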

Results

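Gene expression was measured in the white adipose tissue of female C57BL/6 mice, an inbred laboratory strain, aged 9 months, after normal chow or a diet with 60% of its energy from fat. The sample labels describe each diet as fed for 9 months. The study set chow mice beside high fat mice of 3 successive generations, F0, F1 and F2. Each of the 4 groups was 1 array: the chow array held RNA mixed from 3 samples and each high fat array RNA mixed from 4 samples. Of 45281 probes, 39.8% were detected on the chow array, 38.5% on the F0 array, 37.8% on the F1 array and 40.9% on the F2 array, which left 11384 genes. With 1 array per group a difference between 2 arrays has no replicate check, and the number of arrays limits the precision. Such differences are described by size, and a gene was counted where the arrays were at least 2-fold apart and the brighter one detected it. A fold given as "at least" belongs to a gene detected on the brighter array alone and set against the lowest detected signal of the other. Medians of lists are also given with undetected genes at that bound where this moves them clearly. The SD of the log2 difference between probes of the same gene, the 1 technical gauge these arrays offer, was 0.305 for F0 against chow, 0.290 for F1 against chow and 0.314 for F2 against chow.

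The F0 array addressed the effect of the diet in the founding generation. Macrophage transcripts were higher on it than on the chow array. Of 21 macrophage markers 17 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.69 ± 0.20 (SE over the genes), at percentile 100 of the random lists. Fatty acid and triglyceride synthesis went the other way, with 13 of 23 genes at least 2-fold lower and a median of -1.24 ± 0.31. Leptin, the adipocyte hormone that reports fat mass, was 6.05-fold higher, whereas adiponectin differed by 0.04 on the log2 scale.

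Among the macrophage markers, Tyrobp, a signalling adaptor of myeloid cells, was 8.05-fold higher, Ms4a7 6.44-fold and the lysozyme gene Lyz2 5.03-fold. Genes of lipid-associated macrophages had a median of 1.34 ± 0.41 over 17 genes. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, was 17.1-fold higher (4.09 on the log2 scale, and 3.40 over the mean of its probes), Trem2 5.70-fold, and the macrophage elastase gene Mmp12 at least 28.3-fold. Cell cycle genes were also higher, 12 of 21 by at least 2-fold with a median of 1.18 ± 0.23. Of 31 cytokine and chemokine genes 14 were at least 2-fold higher and 4 lower, with Ccl3 5.64-fold and the acute phase gene Saa3 6.27-fold higher. Toll-like receptors and their adaptors had a median of 0.49 ± 0.23, with 8 of 24 genes at least 2-fold higher, among them Tlr13 at 7.01-fold. Tlr2 differed by 0.03, and Tlr1, not detected on the chow array, lay at 6.03 on the F0 array. Complement genes had a median of 0.98 ± 0.33 (0.65 at the bound), with C1qb 2.83-fold higher and C2 3.06-fold lower, while genes of alternatively activated macrophages lay at -0.24 ± 0.27, at percentile 5.58.

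Within fatty acid synthesis, Elovl6, an elongase of long-chain fatty acids, was 23.9-fold lower by its brightest probe (a log2 difference of -4.58, and -2.86 over the mean of its probes), Fasn, the fatty acid synthase, 7.31-fold, Acly, which makes cytosolic acetyl-CoA, 6.13-fold and Thrsp, a regulator of lipogenesis, 5.37-fold. Scd1, a desaturase, differed by 0.06. Markers of adipose expansion had a median of 1.97 ± 1.02 over 10 genes. The imprinted gene Mest was 23.3-fold higher and Sfrp5, a secreted Wnt antagonist, at least 50.2-fold, against 4.72-fold lower Dlk1. Adipocyte markers had a median of 0.31 ± 0.20 over 20 genes and lipolysis genes 0.31 ± 0.24 over 12, and mitochondrial fatty acid oxidation genes 0.00 ± 0.13. Brown and beige adipocyte markers had a median of -0.57 ± 0.49, and -0.21 with undetected genes at their bound, inside the range of random lists, with the uncoupling protein gene Ucp1 5.60-fold and Cidea 6.13-fold lower.

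The largest increases among genes detected on both arrays were those of Ubd, a ubiquitin-like protein induced by inflammatory cytokines, at 43.6-fold, Mest and Gpnmb. The brain-type tryptophan hydroxylase gene Tph2 was at least 94.0-fold higher and the leukocyte integrin gene Itgad at least 30.6-fold. The largest decreases were 81.2-fold for Ccl21a and 76.2-fold for Ccl21c, which encode near-identical lymphatic chemokines whose probes may share transcripts, so the values of each are uncertain. Genes of other tissues stood among the decreases too. Mesothelial markers had a median of -2.54 ± 0.40 over 12 genes (-2.30 at the bound), with Upk3b 19.9-fold and Upk1b 18.3-fold lower. Skeletal muscle markers had a median of -1.69 ± 0.46 over 17 genes (-1.51 at the bound), and the muscle calcium pump gene Atp2a1 was at least 16.5-fold lower. Smooth muscle genes, a list drawn up after the data were seen, had a median of -2.52 ± 0.49 over 18 genes, with the smooth muscle actin gene Actg2 22.4-fold and the myosin gene Myh11 15.8-fold lower.

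In all, 763 genes were at least 2-fold higher and 756 lower on the F0 array, and the split was 756 to 1216 with the authors' value table and 621 to 951 with median scaling. The total of 1519 became 871 without background correction, 920 with an offset of 50 and 3444 at 1.5-fold (1705 higher and 1739 lower).

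On the F1 array macrophage and cell cycle transcripts were higher than on chow, lipid synthesis transcripts lower and hepatocyte transcripts higher. Mast cell markers, below the random lists on the F0 array, lay inside them here with a median of 0.07 ± 0.29. Macrophage markers had a median of 1.87 ± 0.22, with 19 of 21 at least 2-fold higher, and cell cycle genes a median of 1.58 ± 0.23, with 16 of 21 higher. Fatty acid and triglyceride synthesis genes had a median of -1.18 ± 0.30, with 14 of 23 lower. Ttr, the thyroxine carrier of plasma, was 37.0-fold higher than on the chow array, the apolipoprotein gene Apoa2 35.1-fold and Serpina1b, an antitrypsin gene, 21.9-fold.

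Ttr, Apoa2 and Serpina1b belong to a list of 42 hepatocyte genes, drawn up after the data were seen. Of these 42, 33 were at least 2-fold higher and 1 lower on the F1 array, with a median of 1.87 ± 0.30 (1.63 at the bound). Members were kept where at least 1 array detected them: 42 on the F2 array and 35 on F1, against 21 on F0 and 15 on chow. Counts and medians of this list, here and below, thus partly follow from the choice of its members and test nothing. Serpina1b has close paralogs, and its value may include their transcripts. Among inflammatory genes, the chemokine gene Ccl4 was higher by 4.00 on the log2 scale (3.40 over the mean of its probes), Ccl3 11.6-fold higher and Saa3 9.65-fold. Gpnmb was 19.3-fold (4.27, and 3.74 over the mean of its probes), Ubd 37.0-fold, Dpep2 22.8-fold (a log2 difference of 4.51, and 2.99 over the mean of its probes) and Leptin 6.10-fold higher, and Tph2 at least 119-fold. Elovl6 was 21.8-fold lower (-4.45 on the log2 scale, and -2.81 over the mean of its probes), Fasn 7.11-fold and Ptn, the growth factor pleiotrophin, 27.3-fold. The mesothelial median was -2.10 ± 0.32 (-2.00 at the bound), the skeletal muscle median -1.79 ± 0.44 (-1.59 at the bound) and the smooth muscle median -2.45 ± 0.49, with the muscle PDZ and LIM domain gene Pdlim3 25.6-fold and Tagln 15.5-fold lower.

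The counts for F1 against chow were 840 genes higher and 718 lower, 853 to 1122 with the authors' value table and 762 to 847 with median scaling. The total of 1558 became 935 without background correction, 982 with an offset of 50 and 3453 at 1.5-fold.

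The F2 array differed most from chow by count, and lymphocyte transcripts joined the macrophage and hepatocyte ones. All 14 B cell and plasma cell markers were at least 2-fold higher, with a median of 3.26 ± 0.41 (3.17 at the bound), against medians of 0.25 ± 0.36 on the F0 array and 0.10 ± 0.43 on the F1 array (0.16 and 0.17 at the bound). T cell markers had a median of 1.69 ± 0.41 (1.56 at the bound), with 13 of 19 at least 2-fold higher. Macrophage markers had a median of 2.31 ± 0.25, and fatty acid and triglyceride synthesis genes one of -1.69 ± 0.31, with 18 of 23 lower.

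Fcmr, a receptor for immunoglobulin M, was 46.4-fold higher than on the chow array, Cd79b, a chain of the B cell receptor complex, 26.9-fold and Mzb1, a chaperone of antibody-secreting cells, 18.3-fold. Among T cell genes Cd3e was 10.8-fold higher and Cd27 14.6-fold. Cd276, an inhibitory ligand that stands in the same list but does not mark T cells, differed by -0.43. The signalling adaptor gene Lat, not detected on the chow array, lay at 7.42 on the F2 array. Genes of lymph node stroma and lymphatics spread widely on this array, with 4 of 10 at least 2-fold higher and 3 lower. Glycam1, the mucin of high endothelial venules, was at least 56.8-fold higher, the chemokine gene Ccl19 12.7-fold higher and Lyve1, a lymphatic receptor, 2.49-fold lower. Dendritic cell and MHC class II genes had a median of 1.44 ± 0.34, with 11 of 15 at least 2-fold higher. Mmp12 was at least 72.0-fold and Cd72 24.5-fold higher.

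Of the 42 hepatocyte genes, all detected on the F2 array and 15 on the chow array, 39 were at least 2-fold higher on the F2 array. Their median was 2.51 ± 0.36 (2.20 at the bound). Apoa2 was 110-fold higher, Ttr 76.5-fold and Serpina1b 47.3-fold, and the pituitary hormone gene Prl, which encodes prolactin, at least 74.7-fold. With Apoa2 at 4.83 and Ttr at 4.92 on the chow array, near its lowest detected signal of 4.82, these 2 folds depend on the background step. Their log2 differences of 6.78 and 6.26 became 5.50 and 5.04 without background correction, and 7.55 and 7.12 with the authors' value table. On the side of decreases, Elovl6 was 30.0-fold lower (-4.91 on the log2 scale, and -2.99 over the mean of its probes), Fasn 12.1-fold and Cidea 11.8-fold, and Ucp1 at least 12.1-fold, while Thrsp differed by -3.59 on the log2 scale (-2.83 over the mean of its probes). Clock genes had a median of -1.09 ± 0.28, with 7 of 12 at least 2-fold lower, among them the clock output gene Dbp at 3.85-fold. Endothelial markers had a median of -0.72 ± 0.18 and adipocyte markers one of -0.48 ± 0.22, with the resistin gene Retn 3.50-fold and the insulin-responsive glucose transporter gene Slc2a4 3.32-fold lower. The mesothelial median was -1.89 ± 0.39, the skeletal muscle median -1.98 ± 0.42 (-1.58 at the bound) and the smooth muscle median -2.44 ± 0.31.

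On the F2 array 1064 genes were at least 2-fold higher than on the chow array and 938 lower, and the split was 1171 to 1241 with the authors' value table. The total of 2002 became 1241 without background correction, 1309 with an offset of 50 and 4091 at 1.5-fold, where the direction turned to 1888 higher and 2203 lower.

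**Figure D1:**
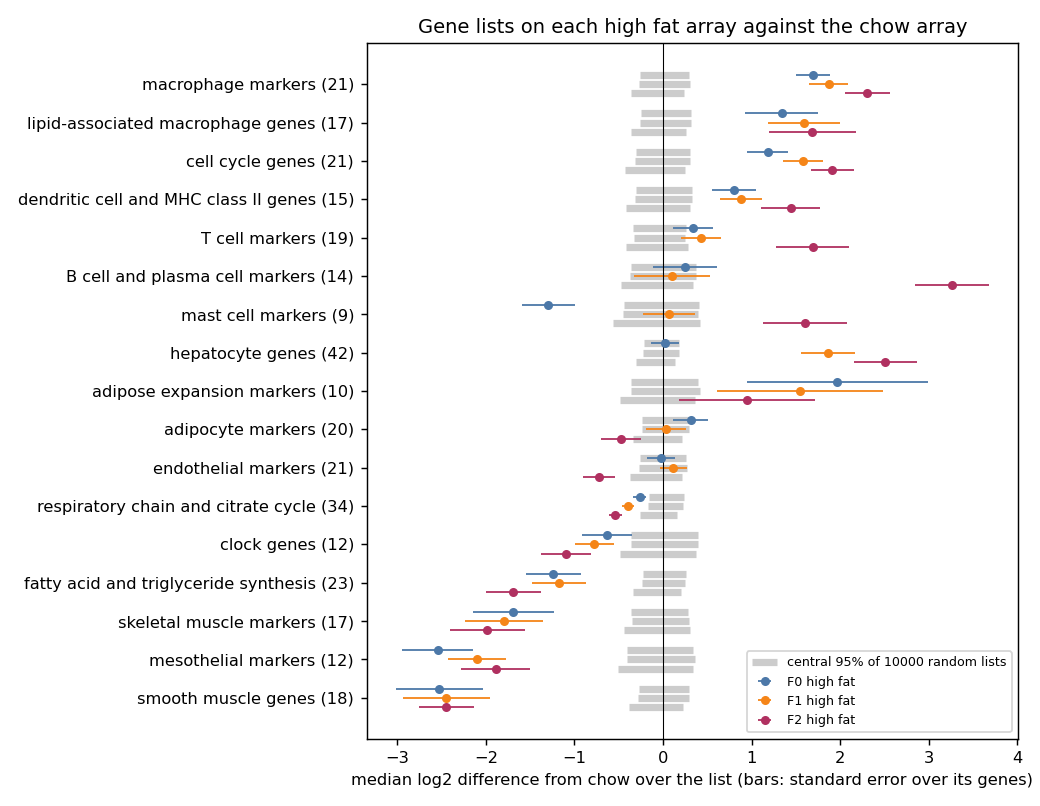
Median log2 difference from the chow array for 17 gene lists on the F0, F1 and F2 high fat arrays, with the number of genes in parentheses, the standard error over genes as bars and the central 95% of 10000 random lists matched on signal in grey. Macrophage markers lie at 1.69, 1.87 and 2.31 and B cell markers at 0.25, 0.10 and 3.26, while mesothelial markers lie at -2.54, -2.10 and -1.89; the hepatocyte and smooth muscle lists were drawn up after the data were seen.

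Across the 3 generations, 463 genes were at least 2-fold higher than chow on all 3 high fat arrays and 499 lower. Across genes the log2 differences from chow correlated at r = 0.921 between F0 and F1, 0.736 between F0 and F2, and 0.838 between F1 and F2. All 3 share the 1 chow array, and unchanged groups simulated against it, with the spread among the 3 high fat arrays and so with the differences between generations in it, correlated at 0.489, 0.494 and 0.486. The covariances were 0.578, 0.525 and 0.617, against simulated values of 0.0759, 0.0742 and 0.0735. F0 and F1 shared 612 higher genes, where independent lists would share 56.3 and simulated unchanged groups 37, and 593 lower genes against 47.7 and 32. F0 and F2 shared 487 higher genes (71.3 and 40) and 545 lower ones (62.3 and 33), and F1 and F2 647 (78.5 and 45) and 580 (59.2 and 36). The chow array cannot be split, so part of the excess may come from it.

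With the high fat arrays taken as 3 samples of the diet against 1 chow array, 331 genes rose and 390 fell by limma after adjustment over all genes. The chow side has no spread of its own, so anything peculiar to that 1 pool, such as its muscle, mesothelial or lymphatic content, counts here as diet. Of the 721 calls, 54 were not detected on the chow array, 95 were detected on no high fat array, and 687 were also called with undetected signals at their bound. The lipid-handling genes Elovl6 and Acly fell and the macrophage genes Gpnmb, Slc15a3 and Itgad rose. Each of the genes named below had all 3 high fat arrays on the same side of chow. Tph2, not detected on chow, rose by 6.65 ± 0.21 with chow at its bound (log2, limma's SE, adjusted p = 0.00703), Ubd by 5.19 ± 0.25 and Gpnmb by 4.30 ± 0.21 (limma, adjusted p = 0.0130 for both). Slc15a3, a lysosomal peptide transporter, rose by 4.02 ± 0.19 and Hp, haptoglobin, by 2.56 ± 0.17 (limma, adjusted p = 0.0130 and 0.0146). Elovl6 fell by 4.65 ± 0.25 (limma, adjusted p = 0.0130) and Acly by 2.65 ± 0.16 (limma, adjusted p = 0.0146). The muscle gene Flnc fell by 3.24 ± 0.20 (limma, adjusted p = 0.0146), and Atp2a1, detected on chow alone, by 4.07 ± 0.21 at the bound (limma, adjusted p = 0.0103). Leptin rose by 2.38 ± 0.31 (limma, adjusted p = 0.0234), Adgre1, the F4/80 macrophage antigen, by 2.51 ± 0.38 (limma, adjusted p = 0.0315), Ccl2, a monocyte chemokine not detected on chow, by 1.66 ± 0.27 with chow at its bound (limma, adjusted p = 0.0343), and Fasn fell by 3.10 ± 0.38 (limma, adjusted p = 0.0209).

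By group, 11 of 21 macrophage markers rose over all genes and 19 adjusted over the list alone, and 9 of 17 lipid-associated macrophage genes and 12 adjusted over the list alone. Of 23 fatty acid and triglyceride synthesis genes 8 fell, and 16 adjusted over the list alone. Of 21 cell cycle genes 8 rose, and 15 adjusted over the list alone, with Cdk1, the mitotic kinase, up by 2.37 ± 0.21 (limma, adjusted p = 0.0146). Of 7 genes of sex hormone action 3 fell, and 4 adjusted over the list alone, with the oestrogen receptor gene Esr1 down from a log2 signal of 8.93 to 6.63, 5.76 and 5.87 and its target Greb1, detected on chow alone, falling by 2.37 ± 0.17 at the bound (limma, adjusted p = 0.0103). Of 12 mesothelial markers 8 fell, and 11 adjusted over the list alone, and of 17 skeletal muscle markers 11, and 15 adjusted over the list alone. Of 12 mammary epithelium markers 5 fell, and 6 adjusted over the list alone. The 5 were Krt7, Krt8, Krt18, Krt19 and Cldn4, of which Krt8 and Krt19 stand in the mesothelial list too.

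The camera set test with a preset correlation of 0.01 called 11 of the 43 lists up and 7 down. Macrophage markers had an adjusted p of 6.97e-14 (limma's camera), cell cycle genes 1.81e-11, lipid-associated macrophage genes 2.52e-11, fatty acid and triglyceride synthesis 2.24e-08, skeletal muscle markers 6.04e-09 and mesothelial markers 1.05e-07. With an estimated correlation 0 lists were called, and each of these 6 had adjusted p = 0.743 with an estimated correlation. Skeletal muscle markers had an estimated correlation of -0.061, yet their unadjusted camera p went from 5.62e-10 to 0.0217. The others of these 6 lists had estimated correlations of 0.919 (cell cycle), 0.704 (mesothelial), 0.596 (macrophage), 0.509 (fatty acid and triglyceride synthesis) and 0.217 (lipid-associated macrophage). These lie far above the preset of 0.01, so the preset p-values may be too small. The estimated setting rests on 2 residual degrees of freedom, so its 0 calls do not decide whether correlation between genes explains the preset calls. Cytokines and chemokines (1.51e-05), Toll-like receptors and adaptors (0.000133), MHC class II genes (0.000126), complement (0.00101), clock genes (0.0103), sex hormone genes (0.0111) and mammary markers (0.000291) were called with limma's camera too, each at adjusted p = 0.743 with an estimated correlation. So were respiratory chain and citrate cycle genes (4.41e-05, down) and T cell markers (0.0134, up), each at adjusted p = 0.793 with an estimated correlation, natural killer cell markers (0.0207) and adipose expansion markers (0.0227), each at 0.761, and B cell markers (0.0262) at 0.837.

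The spread in this fit comes from 3 generations with 2 residual degrees of freedom, and the chow array is assumed to vary like them. The 721 calls became 1 without the F1 array, 1066 without the F0 array and 3178 without the F2 array, and the split of 331 up to 390 down was 144 to 790 with the authors' value table, 280 to 250 among genes detected on all 4 arrays and 570 to 496 without the F0 array. The 1 gene called without F1 was Tph2 (limma, adjusted p = 0.0283), named here after its value was seen.

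**Figure D2:**
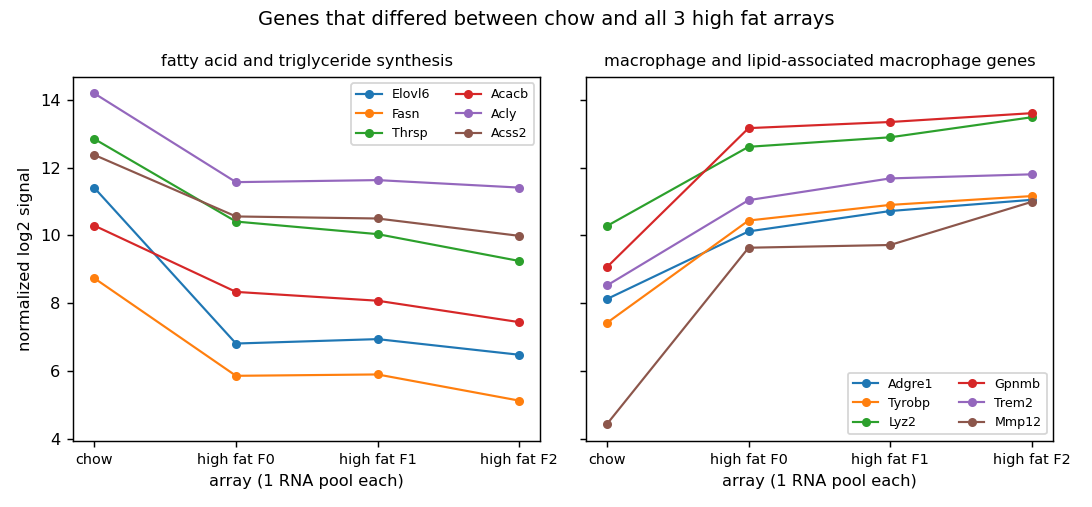
Normalized log2 signal on the 4 arrays, 1 RNA pool each, for 6 fatty acid and triglyceride synthesis genes (left) and 6 macrophage genes (right), joined by lines per gene. Elovl6 goes from 11.40 on chow to 6.82, 6.95 and 6.49 on the F0, F1 and F2 arrays, and Tyrobp from 7.43 to 10.44, 10.90 and 11.16.

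Between generations on the same diet, hepatocyte transcripts were higher on the F1 than on the F0 array. Of 103 genes at least 2-fold apart, 95 were higher and 8 lower on the F1 array. Arrays simulated without change, with differences between generations in their noise, had 205 genes that far apart. Apoa2 was 28.8-fold higher, Itih4, a plasma protease inhibitor, 10.3-fold (3.36 on the log2 scale, and 2.14 over the mean of its probes) and Ttr at least 37.7-fold, and Apoa1, the main protein of high density lipoprotein, differed by 4.00 on the log2 scale. Without background correction the log2 differences of Apoa2 and Apoa1, near the lowest detected signal on the F0 array, were 3.77 and 2.98. They were 5.89 and 4.98 with the authors' value table. The hepatocyte list had a median difference of 1.70 ± 0.26 (1.54 at the bound), with 34 of 42 genes at least 2-fold higher. Ahsg, the fetuin gene, was at least 6.28-fold higher by its brightest probe, undetected on the F0 array, and higher by 1.92 on the log2 scale in the probe detected on both arrays. Cell cycle genes had a median of 0.45 ± 0.05 and macrophage markers 0.29 ± 0.07, both at percentile 100, and adipocyte markers -0.20 ± 0.07 at percentile 0. The neutrophil gene S100a9 was 2.83-fold lower (-1.50 on the log2 scale, and -0.93 without background correction) within a list at a median of 0.14 ± 0.36 (0.04 at the bound), and the fatty acid transporter gene Slc27a1 2.74-fold lower. The total became 46 without background correction, 48 with an offset of 50, 36 among genes detected on all 4 arrays, 474 at 1.5-fold and 65 without the genes of other tissues.

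Among the 43 lists, B cell and lymph node genes had the largest median differences between the F2 and F1 arrays. Without the listed genes of lymphocytes, lymph node, liver, pituitary, muscle and mesothelium 385 of the 444 genes that differ are left, which may hold unlisted genes of the same cells. B cell and plasma cell markers had a median difference of 3.74 ± 0.48 (3.59 at the bound), with 12 of 14 at least 2-fold higher, and 12 of 19 T cell markers were higher too. Genes of lymph node stroma and lymphatics had a median of 1.83 ± 0.88, with 5 of 10 at least 2-fold higher. Fcmr was 31.7-fold higher, Ly6d, a surface protein of early B cells, 18.8-fold, Ccl21a 18.2-fold and Glycam1 at least 52.4-fold, and H2-Ob, a class II chaperone of B cells, differed by 4.00 on the log2 scale.

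Macrophage markers had a median of 0.26 ± 0.11 in this comparison and the hepatocyte list 0.90 ± 0.14, with 18 of 42 at least 2-fold higher and 2, Hamp2 and Hamp, lower. Hamp2, a hepcidin gene whose near-identical copy makes its value uncertain, was 3.43-fold lower. Prl was at least 68.9-fold higher and Gh, the growth hormone gene, at least 21.3-fold. Adipocyte markers had a median of -0.56 ± 0.05, fatty acid and triglyceride synthesis -0.60 ± 0.09 and endothelial markers -0.55 ± 0.12, each at percentile 0. The apelin receptor gene Aplnr was 3.59-fold lower. In all 354 genes were higher and 90 lower. The total of 444 became 213 without background correction, 229 with an offset of 50, 282 among genes detected on all 4 arrays, 667 with the authors' value table and 1662 at 1.5-fold, where the direction turned to 791 higher and 871 lower.

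Set against F0, the F2 array had 524 genes at least 2-fold higher and 288 lower, and the split was 627 to 197 with median scaling. Hepatocyte genes had a median of 2.40 ± 0.31 (2.06 at the bound), with 38 of 42 higher, B cell markers 3.53 ± 0.45 and mast cell markers 2.13 ± 0.54. Apoa2 was 90.3-fold higher, Apoa1 50.3-fold, Fcmr 29.2-fold and Fcer1a, a chain of the immunoglobulin E receptor, 16.4-fold. On the F0 array Apoa2 (5.11) and Apoa1 (5.12) lay near the lowest detected signal of 4.89. Their log2 differences of 6.50 and 5.65 became 5.38 and 4.56 without background correction, and 7.49 and 6.63 with the authors' value table. Ahsg was at least 15.3-fold higher by its brightest probe, undetected on the F0 array, and higher by 3.24 on the log2 scale in the probe detected on both arrays. The growth factor gene Btc was 4.24-fold lower, Amhr2, the receptor of anti-Müllerian hormone, 4.11-fold (-2.04 on the log2 scale, and -1.37 over the mean of its probes) and the imprinted gene Peg3 3.58-fold. On the F2 array Btc, Amhr2 and Peg3 lay at 6.64, 5.89 and 8.24, near their chow signals of 6.48, 5.73 and 8.05. Adipocyte markers had a median of -0.70 ± 0.10, with 8 of 20 at least 2-fold lower, lipolysis genes -0.72 ± 0.19, and adipose expansion markers -1.16 ± 0.38, with 6 of 10 lower. The total of 812 became 406 without background correction, 438 with an offset of 50 and 2620 at 1.5-fold, where the direction turned to 1240 higher and 1380 lower.

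In order of generation, F1 lay between F0 and F2 for 404 of the 524 higher genes, nearer to F0 for 283, and for 274 of the 288 lower genes, nearer to F0 for 228. Choosing genes by the F0 to F2 distance favours F1 between them: it lay there for 77.1% of the higher and 95.1% of the lower genes, and for 67.8% in data simulated with no change. Of those between, 70.0% and 83.2% were nearer to F0, against 50.3% simulated. By limma, with the slope over the 3 generations, 253 genes rose and 212 fell. Each generation is 1 pool here, and the SE reflects departure from a straight line, not spread between pools. Anything in the content of the pools that changes in order of generation, such as hepatocyte or lymph node RNA, counts as slope. Fcer1a rose by 2.02 ± 0.11 log2 units per generation and Serpina1d, an antitrypsin gene with close paralogs, by 1.99 ± 0.11 (limma, adjusted p = 0.00115 for both), and Apoa1 by 2.83 ± 0.28 and Apoa2 by 3.25 ± 0.37 (limma, adjusted p = 0.0151 and 0.0196). Btc fell by 1.04 ± 0.10 and Peg3 by 0.92 ± 0.09 per generation (limma, adjusted p = 0.0151 for both). Their F2 signals of 6.64 and 8.24 lay near those on chow, 6.48 and 8.05.

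Of 9 mast cell markers 6 rose, and 8 adjusted over the list alone, with the protease gene Mcpt4 at 7.23, 9.01 and 10.88 log2 units on the F0, F1 and F2 arrays and Cpa3 at 7.21, 8.86 and 10.78. Of 20 adipocyte markers 10 fell, and 18 adjusted over the list alone, with Lipe, the hormone-sensitive lipase gene, at 10.09, 9.59 and 8.93. Of 21 macrophage markers 7 rose, and 14 adjusted over the list alone. B cell markers had 2 of 14 members rising over all genes, and 13 adjusted over the list alone. Most of their rise lay between the F1 and F2 arrays, where the median difference was 3.74. Fcmr lay at 6.28, 6.16 and 11.15 on the F0, F1 and F2 arrays. Limma's camera gave an adjusted p of 4.22e-10 for adipocyte markers (down), 4.22e-10 for mast cell markers (up), 2.41e-08 for macrophage markers (up) and 2.54e-08 for B cell markers (up), each at adjusted p = 0.572 with an estimated correlation. In all 17 lists were called up and 9 down with the preset correlation, and 0 with an estimated one. Macrophage markers had an estimated correlation of -0.0476, yet their unadjusted camera p went from 1.68e-09 to 0.0956. Adipocyte, mast cell and B cell markers had estimated correlations of 0.621, 0.556 and 1, far above the preset of 0.01, so their preset p-values may be too small. The estimated setting rests on 1 residual degree of freedom, so its 0 calls do not decide whether correlation between genes explains the preset calls. With 1 residual degree of freedom the 465 calls of limma ranged widely, from 0 with the authors' value table (1663 at an unadjusted p under 0.05), 22 without a mean trend and 74 with median scaling (58 up and 16 down) to 1257 without background correction and 1883 with undetected signals at their bound. The split of 253 up to 212 down turned to 213 and 258 with scaling to probes detected on all arrays, 533 and 676 among genes detected on all 4 arrays, and 919 and 964 at the bound.

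**Figure D3:**
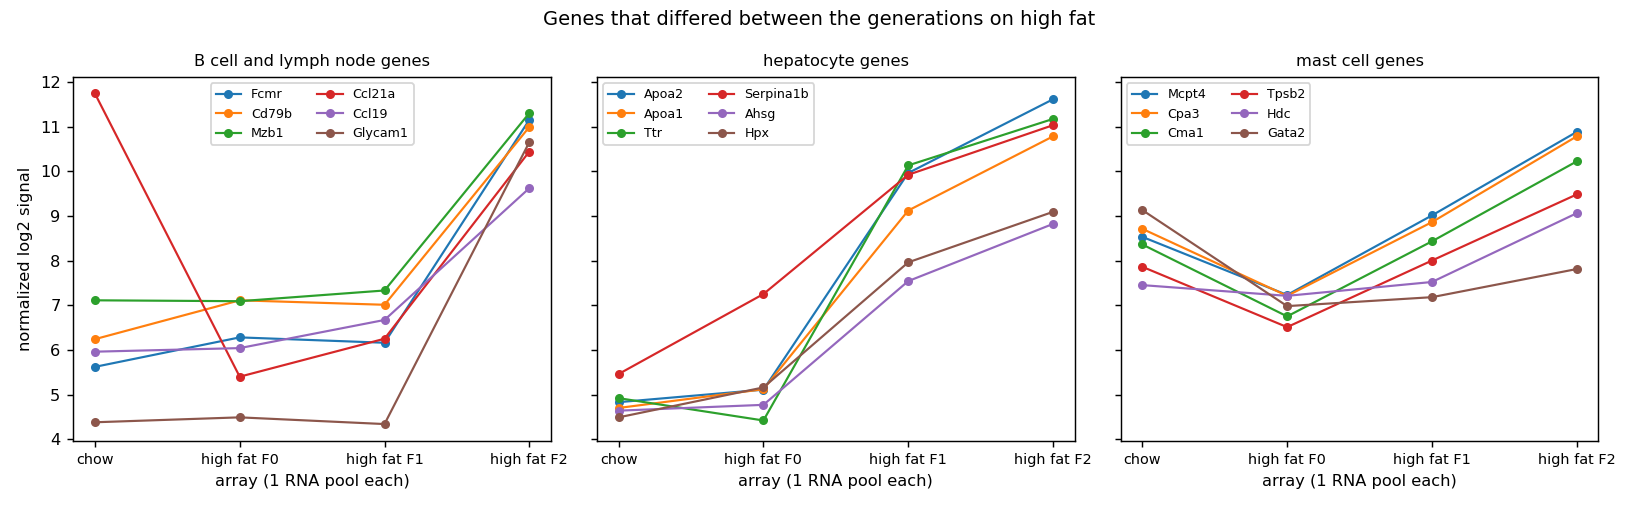
Normalized log2 signal on the 4 arrays, 1 RNA pool each, for 6 B cell and lymph node genes (left), 6 hepatocyte genes (middle) and 6 mast cell genes (right), joined by lines per gene. Fcmr lies at 5.62, 6.28 and 6.16 on the chow, F0 and F1 arrays and at 11.15 on the F2 array, Apoa2 at 4.83, 5.11, 9.96 and 11.61, and Mcpt4 at 8.53, 7.23, 9.01 and 10.88.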

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

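Of the tests in this part, that of lymph node genes, that of macrophage against B cell markers, that of hepatocyte gene ratios and that of pituitary genes were chosen after the result was seen. The pituitary test was written to exclude its explanation when at most 1 gene was detected, and was changed once that had happened to leave it open, because genes at the floor on every array exclude nothing. A count of 4 hepatocyte transcripts picked because they were undetected was also tried and carries no weight. Opposite signs against the chow array rest on 1 array per group and were not tested, whereas the slope over the 3 high fat arrays was, in a limma fit that called 0 genes with the authors' value table.

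Adipocyte markers and mast cell markers stood on opposite sides of chow in F0 and F2. The adipocyte median was 0.31 on the F0 array and -0.48 on the F2 array, and the mast cell median was -1.30 on the F0 array and 1.60 on the F2 array. By limma's slope 6 of 9 mast cell markers rose and 10 of 20 adipocyte markers fell. Each list had a camera adjusted p of 4.22e-10, and adjusted p = 0.572 with an estimated correlation. The latter rests on 1 residual degree of freedom and cannot decide. Over the same arrays the F2 minus F0 median was 2.40 for hepatocyte genes, 3.53 for B cell markers, 2.07 for lymph node genes and -0.69 for endothelial markers. Of the 9 mast cell markers, 8 were detected on the chow array and 0 stand in another list.

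Ly6d differed from chow by -2.05 on the F0 array, -2.78 on the F1 array and 1.45 on the F2 array, signs that were not tested, with a slope over generations that did not pass (limma, adjusted p = 0.116), and it belongs to the lymphocyte genes that were higher on the F2 array. Lymph node tissue in the F2 pool is a candidate explanation, since the lymph node stroma and lymphatic list had a median F2 minus F1 difference of 1.83, with Glycam1 at 10.65, Ccl21a at 10.44 and Ccl19 at 9.62 log2 units on the F2 array, although 5 of its 10 genes stand in other lists and 8 were detected on the chow array. For these pools, a rise of all immune cells alike is argued against by the macrophage median of 0.26 beside 3.74 for B cells. The macrophage median was short of a 0.5 share of the B cell median by 1.61 ± 0.27. This SE is over genes, which are not independent, and does not measure spread between pools. The background or scaling step is argued against by B cell medians from 2.71 to 4.13 over 3 alternatives. The 14 B cell markers, 10 of them detected on the chow array and 0 in another list, were led by Mzb1 at 11.30 and Fcmr at 11.15. A generation difference in the lymphocytes of the tissue itself stays open beside an adhering lymph node, and the chow array, with Ccl21a at 11.74, may hold lymphatic tissue of its own.

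Itih4 differed from chow by -1.48 on the F0 array, 1.88 on the F1 array and 2.26 on the F2 array, signs that were not tested, and its slope over generations was 1.87 ± 0.35 (limma, adjusted p = 0.0464). Of 49 hepatocyte genes with a probe, 42 were detected on the F2 array, 15 of them on the chow array and 1 in another list, and the highest on F2 were Apoa2 at 11.61, Ttr at 11.17, Cyp2e1 at 11.10 and Serpina1b at 11.03. RNA of hepatocytes in the F1 and F2 pools cannot be told apart from other sources, since the F2 to F1 ratios of 35 hepatocyte genes had an SD of 0.83 (95% bootstrap interval 0.47 to 1.12). Alb (4.41), Fabp1, Fgb and Serpinc1 were not detected on the F2 array. They were picked for that, and the response of their probes in liver is not known here, so they carry no weight. RNA of several organs in the F2 pool cannot be told apart either: Prl lay at 11.04 and Gh at 9.35 there, and 0 of 6 other pituitary genes were detected on it alone, but those 6 lay at the floor on every array and cover 1 organ. Over 3 alternatives to the background or scaling step the hepatocyte median for F2 against F0 ran from 1.53 to 2.81. All 42 members were detected on the F2 array and 21 on the F0 array, so their choice favours such a median. It therefore does not decide on that step, and a difference between generations may remain.

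Probes without a single gene symbol, which the comparisons leave out, also carried signal. Of 10396 such probes, 152 were at least 2-fold higher than chow on the F0 array, 163 on the F1 array and 346 on the F2 array, against 219, 210 and 200 lower.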

How the results depend on the processing

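Scaling to the probes detected on all arrays, the counts without the genes of other tissues, undetected signals at their bound and detection of the brightest probe itself were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group has 1 array.

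Counts of genes at least 2-fold apart, for F0, F1 and F2 against chow and for F1 against F0, F2 against F1 and F2 against F0, were 871, 935, 1241, 46, 213 and 406 without background correction, where the undiminished background compresses ratios by construction. An offset of 50 gave 920, 982, 1309, 48, 229 and 438, and a threshold of 1.5-fold, which is wider by construction, gave 3444, 3453, 4091, 474, 1662 and 2620. The authors' value table gave 667 for F2 against F1, genes detected on all 4 arrays 36 for F1 against F0 and 282 for F2 against F1, and leaving out genes of other tissues 65 for F1 against F0. The other counts stayed within 1.5 times.

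The diet fit of limma called from 1 to 3178 genes when 1 high fat array was left out. Of the 721 calls, 680 stayed without F0, 1 without F1 and 721 without F2. All 721 kept their sign each time, which says little, since they were chosen on these same arrays and set against the same chow array. The slope fit of limma, with 465 calls, gave 0 with the authors' value table, 1257 without background correction, 74 with median scaling, 904 with an offset of 50, 1209 among genes detected on all 4 arrays, 906 with no detection filter, 1883 with undetected signals at their bound and 22 without a mean trend. This fit has 1 residual degree of freedom; the cause was not tested.

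Under alternatives, 902 list results were checked, for lists outside the central 95% of random lists in the main processing alone. They cover F0, F1 and F2 against chow and F2 against F0. Of these, 789 moved by less than 1 standard error, 113 moved by more and 0 reversed. Undetected signals at their bound, under which some list medians changed sign, were not among these alternatives. The authors' table put the T cell median for F0 against chow (0.34, and 0.23 at the bound) and the mammary median for F2 against F0 (0.31, and -0.09 at the bound) at 0. Of the 112 named differences, 112 stayed at least 2-fold with the authors' table, 111 with median scaling, 110 with the mean of probes and 107 without background correction. Their size moved by at least 1.5-fold for 31, 0, 24 and 70 of them in that order. Median scaling moved the median of all genes to -0.109 for F0 against chow and -0.111 for F2 against chow, from -0.013 and -0.095.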

Other observations

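The test of adipocyte against muscle and mesothelial genes in this part was chosen after the result was seen. Respiratory chain and citrate cycle genes had medians of -0.27, -0.40 and -0.54 on the F0, F1 and F2 arrays over 34 genes, below the random lists on each. Fatty acid oxidation genes, at 0.00, -0.24 (-0.11 at the bound) and -0.35 over 18, lay inside the central 95% of random lists on each array. Between generations they lay below the random lists, with medians of -0.22 for F1 against F0, -0.26 for F2 against F1 and -0.53 for F2 against F0. Insulin signalling genes had medians of -0.26, -0.39 and -0.29 over 15, and 0.04 on F0 and -0.22 on F1 with undetected genes at their bound, so no direction is read from them, and within them the regulatory subunit gene Pik3r1 fell by 1.26 ± 0.15 (limma, adjusted p = 0.0206). Interferon-stimulated genes had medians of 0.01, 0.09 and 0.37 and natural killer cell markers 0.56, 0.20 and 0.90, the former inside the random lists on F0 and F1. Hmox1, the inducible haem oxygenase, rose by 3.20 ± 0.50 and Gsta4 fell by 3.14 ± 0.32 (limma, adjusted p = 0.0343 and 0.0177) within an oxidative stress list with medians of 0.34, 0.20 and 0.23. Atf3 rose by 2.61 ± 0.23 (limma, adjusted p = 0.0146) in an endoplasmic reticulum stress list with medians of -0.04, 0.20 and 0.28, the last 0.15 at the bound and inside the random lists. In the DNA methylation list, inside the random lists on each array with medians of -0.05, 0.05 and -0.13, Gadd45b rose by 1.92 ± 0.23 (limma, adjusted p = 0.0206) and the maintenance methyltransferase gene Dnmt1 differed by 0.07, 0.50 and 0.73. Vegfa, the vascular growth factor gene, was at 9.85 on chow and 9.30, 8.76 and 7.87 on the F0, F1 and F2 arrays, beside hypoxia medians of -0.10, -0.15 and -0.31, inside the random lists on each array. Arg1, arginase of macrophages and liver, lay at 6.38, 7.41 and 8.26 on the high fat arrays.

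The remaining lists are given for completeness. Medians on the F0, F1 and F2 arrays against chow were -0.29, 0.06 and -0.26 for extracellular matrix genes, -0.35, -0.12 and -0.31 for progenitor and fibroblast markers, 0.18, 0.36 and 0.18 for cholesterol synthesis, -0.04 (0.07 at the bound), 0.10 and 0.45 for immediate early genes and 0.49, -0.19 and 0.44 for neutrophil markers (0.01 on F1 and 0.32 on F2 at the bound). They were -0.35, -0.23 and -0.02 for ribosomal protein genes, -0.19, -0.10 and -0.17 for reference genes, -0.38, -0.28 and -0.50 for ovary markers and 0.15, -0.11 and -0.37 for pancreas markers (-0.21, -0.12 and -0.36, and 0.08, 0.12 and -0.05, at the bound), -0.56, 0.04 and 0.28 for red blood cell genes and -0.30, -0.14 and 0.16 for nerve and glia markers. The 2 pituitary genes kept, Prl and Gh, were detected on the F2 array alone, with a median difference from chow of at least 5.38. Against chow the clock median was -0.63 on F0 and -0.78 on F1, and that of sex hormone genes -0.96, -1.09 (-0.89 at the bound) and -0.86. Tnf and Itgax, not detected on the chow array, lay at 5.74 and 5.35 on the F2 array.

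Skeletal muscle, smooth muscle and mesothelial genes were lower on all 3 high fat arrays. The adipocyte median lay above that of these 47 genes by 1.67 ± 0.31 at the smallest and 2.71 at the largest. This SE is over genes, which are not independent, and does not measure spread between pools. The smooth muscle genes were listed after the data were seen, which favours such a gap. Over the 3 high fat arrays the planned skeletal muscle and mesothelial lists had median differences from chow of -1.77 and -2.22, beside -0.10 for adipocyte markers. For these pools, this argues against dilution by RNA of added immune cells as the only cause for those lists. Adipocyte markers are no neutral reference, since some differed from chow themselves, such as Lep by 2.60 on the F0 array. A larger piece of skeletal muscle in the chow pool cannot be told apart from other causes, because the F0 to chow ratios of 11 muscle genes had an SD of 1.85 (95% bootstrap interval 0.89 to 2.33) and ranged from -4.38 to 1.45. All 17 skeletal muscle and 12 mesothelial markers were detected on the chow array, led by Myl1 at 11.66, Acta1 at 10.31 and Upk3b at 11.65, as were 17 of 18 smooth muscle genes, led by Acta2 at 14.51. A difference in the dissected depot or an effect of the diet may each remain, untested.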
